A study of Arabidopsis thaliana with 6 samples.

How the data were processed

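Gene expression was measured with Affymetrix arrays in leaf tissue of Arabidopsis thaliana, 3 arrays from plants that express AmGSTF1 and 3 from wild-type plants of the ecotype Col0. Each sample was put in its group by the transgene its label names, and the replicate number was taken from its title. Per the labels' protocols, seeds were kept cold (4 °C) for 72 hours, and plants grew on compost at 20 °C with 16 hours of light a day. For each replicate, 10 leaves lay for 4 hours on water with 0.1% Tween 20 and 0.1% acetone before they were frozen. The labels call the replicates biological. How many plants gave the leaves, and whether samples were handled in batches, is not given in the sources used here.

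The deposited values are MAS5 signal intensities on a linear scale, made with Affymetrix Expression Console 1.1, per the submitters' processing notes. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal. The mean signal after trimming 2% of probe sets at each end was 495 to 496 on every array, so the arrays share 1 scale. No detection calls were used here, so a low signal was not separated from background. The number of arrays limits the precision of all values.

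No further normalization was applied. The 22746 probe sets were taken as log2(signal + 16), and the 40% with the lowest mean log2 over the 6 arrays were left out, which left 13647. A difference on this scale understates the change of dim probe sets. AmGSTF1 was compared with Col0 per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with no replicate term. All p-values are two-sided unless said otherwise, and a probe set was called where its Benjamini-Hochberg adjusted p was under 0.05. Intervals are 95% confidence intervals from limma. An exact permutation test of 3 arrays against 3 cannot give a p under 0.1, so none was run on single genes. Figures were drawn with Python 3.11.15.

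Probe sets were named through the platform annotation and the RefSeq gene table of assembly TAIR10.1, which was used for names and for which genes are neighbours. The annotation gave 1 gene for 13513 probe sets and several for 503, and 8730 were unnamed here. Of the probe sets kept, 7355 had 1 gene, and only these are named. Genes without a symbol in the table go by their locus identifier, and of those in a gene list only the list, or the symbol it writes, is given.

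Before the data were examined, 25 gene lists with 512 genes were fixed: 5 on detoxification, redox and flavonoid genes, 14 on other processes and 6 of cell type markers. A member was matched by locus and symbol, and 6 entries whose symbol did not match were dropped. Where the table gives a locus no symbol, the member was kept by locus (7 genes). Only 80 of the 512 genes had a named probe set, and 56 were bright enough to be kept. Each gene was represented by its brightest probe set. Lists with at least 3 measured members, a minimum chosen after the data were seen, were tested with camera at a preset correlation of 0.01, adjusted over the 10 lists tested. Alternatives were camera with an estimated correlation and fry. Camera with an estimated correlation also uses fewer degrees of freedom, so a larger p from it does not measure correlation alone.

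Genes were named by a rule fixed before the data were examined. It takes the 10 largest called rises and the 10 largest called falls among probe sets with 1 gene whose groups do not overlap. Had a direction had fewer than 10, the next by p among non-overlapping probe sets would have been named as having missed the threshold. It also takes the 3 members with the smallest p from each of the first 5 lists and 1 from each other list, called or not, and up to 4 where more were called. Genes outside the rule are said to be chosen after their values were seen.

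The alternatives tried were other pseudocounts, filters and normalizations between arrays, limma without the trend, with robust estimates or with array weights, a replicate block, and leaving out each array. Others were stricter and looser thresholds, list tests with all probe sets and list members without a table symbol dropped. The last of these was chosen after the data were seen. A comparison of RNA quality by control probe sets was not run, because the table analysed here held no control rows. No probe set was assigned to the transgene, so its level was not used to check the labels.

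The steps were tested on simulated data drawn from the means and spreads of the 13647 probe sets for AmGSTF1 against Col0, in 10 simulations with 200 changed probe sets each. Of the changes of 0.5, 1 and 2 on the log2 scale, 4.05%, 66.6% and 97.7% were called, and 4.54% of the calls were false. A list shifted as a whole by 1 on the log2 scale was called in 10 of 10 simulations, and other lists were called in 5 of 90 tests. Probe sets were drawn independently of each other, whereas the estimated correlation in the glucosinolate list was 0.883. These shares therefore do not give the error under correlated probe sets. They also hold for 200 changed probe sets, fewer than the 688 called in the data, and the share called depends on that number.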

Results

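Transcript levels were compared between leaves of Arabidopsis plants that express AmGSTF1, a glutathione transferase from a grass weed, and leaves of wild-type Col0 plants. The series concerns the part of this enzyme in resistance to several herbicides, and the comparison asks which of the plant's own genes differ in expression when the enzyme is present. All leaves had floated on the same mild detergent and solvent solution for 4 hours, and no herbicide is named for any sample. There were 3 arrays per group, each from a separate biological replicate. The median signal was 146 to 150 on the Col0 arrays and 151 to 164 on the AmGSTF1 arrays. Across the 13647 probe sets kept, arrays of a group correlated at r = 0.963 to 0.977 and arrays of different groups at 0.932 to 0.965 (across probe sets, which are not independent replicates). The median SD between replicates was 0.20 on the log2 scale in both groups.

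**Figure D1:**
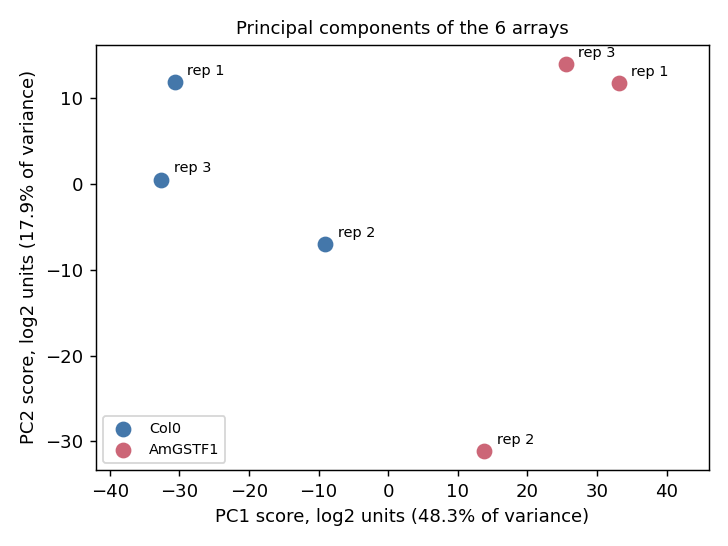
Principal components of log2(signal + 16) over the kept probe sets, with the score on the first component (48.3% of the variance) against the second (17.9%). Points are the 6 arrays. The Col0 arrays lie between -32.6 and -9.03 on the first component and the AmGSTF1 arrays between 13.7 and 33.1, with replicate 2 of each group nearest the other group.

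In AmGSTF1 leaves, 292 probe sets rose and 396 fell. The largest rise was that of AT3G62550, from a Col0 signal of 632 ± 441 to 6901 ± 1913 (SD, n = 3), which is 12.1-fold on the log2(signal + 16) scale. AT1G56220 rose 7.78-fold on that scale. CYP51G2, a cytochrome P450 of the family that demethylates sterols, also rose, from Col0 signals too low for a fold to be given. The largest falls among named genes were those of CSLA01, a cellulose synthase-like glycosyltransferase, and MSRB6, a methionine sulfoxide reductase that repairs oxidised methionine. They fell by 1.98 and by 1.89 on the log2 scale. CSLA01 went from 2365 ± 487 in Col0 to 598 ± 182 (SD, n = 3), and MSRB6 from 4401 ± 816 to 1229 ± 517.

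The other large rises were AT5G24490 (log2 difference 2.43), AT1G43590 (2.42), AT5G18600 (2.29), AT4G32340 (2.28), AT3G47160 (2.09), AT4G14270 (2.04) and AT3G47800 (1.95). Their adjusted p ranged from 0.00393 for AT1G43590 to 0.0486 for AT5G18600. In AT5G18600 the Col0 signals were 145, 913 and 150, so replicate 2 lay near the lowest AmGSTF1 signal of 1195. The call of AT5G18600 was lost in every fit that left out an array except that without Col0 replicate 2, where the difference was 3.12 (adjusted p = 0.000285). Without Col0 replicates 1 and 3 and AmGSTF1 replicates 1, 2 and 3 its adjusted p was 0.167, 0.161, 0.159, 0.0521 and 0.121. It was also lost with a pseudocount of 1 (0.0501), loess normalization (0.0505), no filter on dim probe sets (0.0894), no intensity trend (0.0734) and robust estimates (0.102). AT5G24490 was lost with the last 3 of these settings (0.0697, 0.0611 and 0.0812) and without Col0 replicates 1 and 3 and AmGSTF1 replicates 1 and 3 (0.137, 0.133, 0.121 and 0.0909), and ranged from 1.84 without AmGSTF1 replicate 1 to 3.02 without AmGSTF1 replicate 2. AT1G56220 was lost without Col0 replicate 1 (2.55, adjusted p = 0.0710), Col0 replicate 3 (2.75, 0.0689) and AmGSTF1 replicate 1 (2.85, 0.0804), and the log2 difference of AT1G56220 was 3.58 without Col0 replicate 2. CYP51G2 had signals of at most 24.7 in Col0 against 304 to 412 in AmGSTF1. The signal below which 40% of the probe sets lay was 68.7 to 84.5 on the 6 arrays, so the size of this rise and its place among the others depend on the pseudocount. With a pseudocount of 64 the log2 difference of CYP51G2 was 2.34 and the log2 difference of AT1G56220 was 2.83.

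The other large falls included MSRB9, a relative of MSRB6, which fell by 1.61 on the log2 scale (SE 0.22, adjusted p = 0.0117). CCR2, the cinnamoyl-CoA reductase encoded by AT1G80820, fell by 1.75, and SWEET13, a sucrose transporter, fell by 1.38. Loci without a symbol in the table were AT1G04770 (-1.74), AT3G14200 (-1.66), AT5G44050 (-1.46), AT1G14120 (-1.45) and AT3G12860 (-1.41). The calls of AT5G44050 and AT1G14120 were lost with no filter (adjusted p = 0.0643 and 0.0645) and without the intensity trend (0.0597 and 0.0585). They were also lost without Col0 replicate 1 (0.139 and 0.125), Col0 replicate 3 (0.123 and 0.125), AmGSTF1 replicate 1 (0.147 and 0.123) and AmGSTF1 replicate 3 (0.104 and 0.102). CCR2 was lost without Col0 replicate 1 (-1.58, adjusted p = 0.0933), Col0 replicate 3 (-1.69, 0.0779) and AmGSTF1 replicate 1 (-1.48, 0.0814), and MSRB9 without Col0 replicates 1 and 3 (0.0710 and 0.0606). AT1G04770 had the smallest adjusted p of these 20 genes, 0.00199, with signals of 1215 to 1504 in Col0 and 362 to 427 in AmGSTF1.

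**Figure D2:**
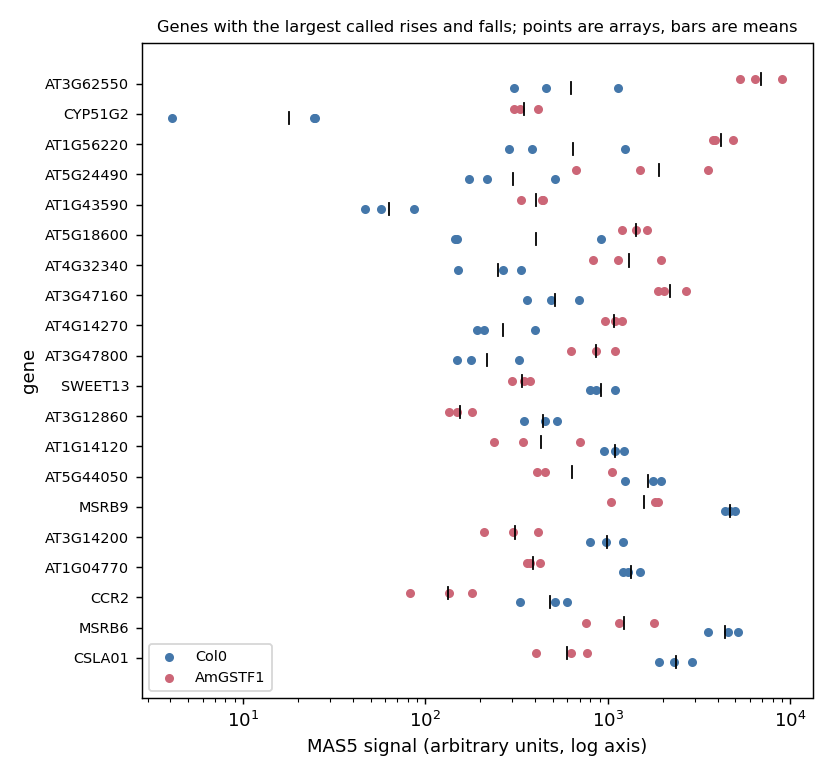
MAS5 signal (log axis) of the 10 genes with the largest called rises and the 10 with the largest called falls. Points are arrays, black bars are group means, and in each gene the 3 AmGSTF1 arrays lie on 1 side of the 3 Col0 arrays. AT3G62550 has the highest AmGSTF1 signals, and the Col0 signals of CYP51G2 lie near the bottom of the scale.

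The calls made up 5.04% of the probe sets tested with limma, and 135 of the rises and 96 of the falls were at least 2-fold. The groups did not overlap for 3765 probe sets (27.6%, where chance gives 10%), and 3179 had an unadjusted p under 0.05. The number of calls depended on single arrays. It was 11 without Col0 replicate 1, 13 without Col0 replicate 3, 17 without AmGSTF1 replicate 1 and 251 without AmGSTF1 replicate 3. However, it was 1133 without Col0 replicate 2 and 1069 without AmGSTF1 replicate 2. In all 688 called probe sets the groups did not overlap, so leaving out an array could not change their sign. Of the 25 called genes named by the fixed rule, 4, 4, 6, 16, 25 and 22 were still called in the same order of omitted arrays, of 24 tested where an AmGSTF1 array was omitted. AT3G62550 was lost without Col0 replicate 3 (adjusted p = 0.0501), CSLA01 without Col0 replicates 1 and 3 (0.0556 and 0.0568) and MSRB6 without these and AmGSTF1 replicate 1 (0.0801, 0.0689 and 0.0745). AT3G47160 was lost without Col0 replicate 1 (0.0556), and AT4G32340, AT4G14270, AT3G47800, AT3G14200, AT3G12860 and SWEET13 were lost without Col0 replicate 1, Col0 replicate 3 or AmGSTF1 replicate 1 (0.0501 to 0.0801). AT1G04770 and AT1G43590 were called in all 6 of these fits, and CYP51G2 in the 3 that omit a Col0 array, where it passed the filter on dim probe sets.

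Glutathione transferases, the enzyme family of the transgene, conjugate glutathione to reactive and foreign compounds. GSTU27 rose by 0.96 on the log2 scale (95% interval 0.47 to 1.45, adjusted p = 0.0380), from a signal of 571 ± 170 to 1106 ± 171 (SD, n = 3). It was the single call among the 7 measured members of this list of 52. GSTU18 differed by -0.40 (-0.98 to 0.18) and GSTF4 by 0.33 (-0.33 to 0.99), and the remaining 4 members lay between -0.01 and 0.25. The list as a whole had a median difference of 0.15 (camera adjusted p = 0.642, or 0.843 with an estimated correlation). Without Col0 replicate 1, Col0 replicate 3, AmGSTF1 replicate 1 or AmGSTF1 replicate 3 the adjusted p of GSTU27 was 0.127, 0.118, 0.146 and 0.117, with differences of 0.75, 0.97, 0.93 and 0.87. The call was also lost with no filter on dim probe sets (0.0643) and without the intensity trend (0.0627).

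Among flavonoid and anthocyanin genes, AT1G06000, which was listed as UGT89C1, fell by 1.07 on the log2 scale (95% interval -1.47 to -0.67, adjusted p = 0.0180). The glycosyltransferases UGT78D1 and UGT78D2 differed by -0.72 (-1.34 to -0.10) and -0.32 (-0.62 to -0.03) without passing over all probe sets, and CHIL by 0.14 (-0.71 to 0.99). Adjusted over the list alone, 3 of these 4 measured members of 25 were lower. The list's median difference was -0.52, and it did not pass (camera adjusted p = 0.0977, or 0.581 with an estimated correlation). At the preset correlation it passed without Col0 replicate 2 (mean difference -0.66, adjusted p = 0.0380) and without AmGSTF1 replicate 2 (-0.57, 0.0485), but without Col0 replicate 3 its mean difference was -0.41 (0.249). UGT78D1 ranged from -0.39 without Col0 replicate 1 (adjusted p = 0.405) to -1.01 without Col0 replicate 2, where it passed (0.0383). The call of AT1G06000 was lost without Col0 replicate 1 (-0.96, adjusted p = 0.0941), Col0 replicate 3 (-1.06, 0.0779) and AmGSTF1 replicate 1 (-0.94, 0.0941).

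Of 7 measured antioxidant enzymes (of 39 listed), 0 passed limma's test over all probe sets and 0 adjusted over the list alone, while 2 had an unadjusted p under 0.05. ATMDAR2, a monodehydroascorbate reductase, differed by -0.44 (-0.77 to -0.11), the glutathione reductase GR1 by -0.28 (-0.56 to -0.01) and the thylakoid ascorbate peroxidase TAPX by 0.20 (-0.09 to 0.50). The other 4 members, GR, SAPX, VTC4 and AT3G11630, lay between -0.33 and 0.25. The median of the list was -0.06 (camera adjusted p = 0.501, or 0.837 with an estimated correlation).

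In glutathione synthesis and sulfate assimilation, SIR, the sulfite reductase, fell by 0.64 (95% interval -0.97 to -0.30, adjusted p = 0.0443). The ATP sulfurylases APS3 and APS4 differed by -0.57 (-1.05 to -0.09) and 0.02 (-0.39 to 0.42). Among xenobiotic metabolism genes, GT72B1, a glucosyltransferase that acts on chlorophenols and chloroanilines, fell by 0.70 (-1.07 to -0.33, adjusted p = 0.0449). NQR, a quinone reductase, differed by 0.56 (0.15 to 0.96) and AER, an alkenal reductase, by -0.48 (-0.87 to -0.09). Each of these lists had 3 measured members, of 29 and 33. Adjusted over the list alone, 2 of the first were lower, and 2 of the second were lower and 1 higher. The lists did not pass (medians -0.57 and -0.48, camera adjusted p = 0.194 and 0.501, or 0.581 and 0.837 with an estimated correlation). The call of GT72B1 was lost without Col0 replicate 1, Col0 replicate 3, AmGSTF1 replicate 1 or AmGSTF1 replicate 3 (differences -0.68, -0.68, -0.52 and -0.79, adjusted p = 0.151, 0.137, 0.139 and 0.0754). That of SIR was lost in these fits and without AmGSTF1 replicate 2 (differences -0.53 to -0.71, adjusted p = 0.0672 to 0.151). With no filter on dim probe sets and without the intensity trend the adjusted p of GT72B1 was 0.0710 and 0.0734 and that of SIR 0.0645 and 0.0729, and SIR was lost with loess normalization (0.0516). NQR passed without Col0 replicate 2 (0.71, adjusted p = 0.0426) and with array weights (0.65, 0.0404), but was 0.37 (0.298) without Col0 replicate 1.

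**Figure D3:**
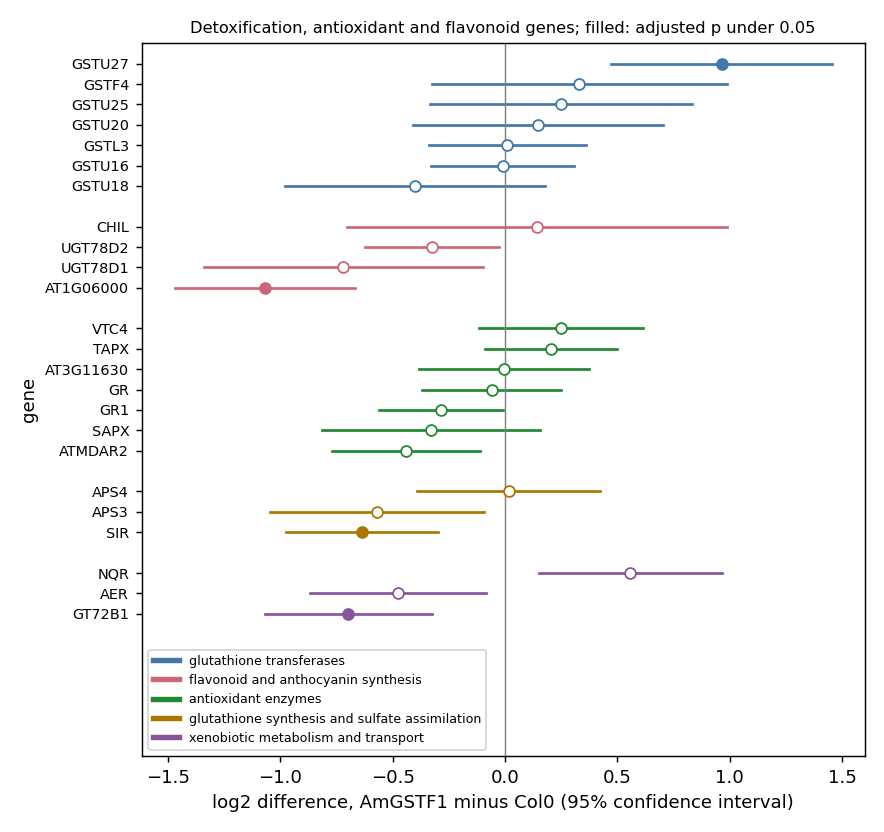
Log2 difference, AmGSTF1 minus Col0, with 95% confidence intervals from limma (3 arrays per group), for the measured members of the 5 lists on detoxification, redox and flavonoid genes. Filled points passed at an adjusted p under 0.05: GSTU27 on the higher side, and AT1G06000, SIR and GT72B1 on the lower.

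Among the other processes, JMT, which methylates jasmonic acid, fell by 1.28 (95% interval -1.80 to -0.76, adjusted p = 0.0214), while the defensin gene PDF1.2 differed by 0.93 (0.06 to 1.79). Adjusted over the list alone, JMT was lower and PDF1.2 higher. These were the 2 measured members of the jasmonate list, too few for a list test. The call of JMT was lost without Col0 replicate 1, Col0 replicate 3, AmGSTF1 replicate 1 or AmGSTF1 replicate 3 (differences -1.26, -1.31, -1.07 and -1.21, adjusted p = 0.0993, 0.0814, 0.0962 and 0.0615). HCT, an acyltransferase of lignin synthesis and the single measured member of the phenylpropanoid list, differed by -0.54 (-0.89 to -0.20), and passed under median centring (-0.60, adjusted p = 0.0479) but in no fit without 1 array (-0.40 to -0.64, 0.0859 to 0.196).

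The abscisic acid, dehydration and cold list had 0 of 5 members called. Its member with the smallest p was LEA4-5, a late embryogenesis abundant protein gene, at 2.09 (0.50 to 3.67). It passed without AmGSTF1 replicate 3 (2.88, adjusted p = 0.0457) but was 1.34 (0.205) without AmGSTF1 replicate 2. The list's median was -0.06 and its mean 0.41, of opposite signs (camera adjusted p = 0.780). In the photosynthesis list 0 of 6 members were called and 5 had higher values, led by the antenna protein gene LHCB4.2 at 0.48 (0.08 to 0.87), with a median of 0.17 and camera adjusted p = 0.501, or 0.843 with an estimated correlation of 0.733. Without AmGSTF1 replicate 2 this list passed at the preset correlation alone (mean difference 0.37, adjusted p = 0.0485), and the estimated correlation was not tried there; without AmGSTF1 replicate 3 the mean difference was 0.10 (0.759). LHCB4.2 passed without AmGSTF1 replicate 2 (0.68, adjusted p = 0.0199) and with array weights (0.54, 0.0494), but was 0.34 (0.402) without AmGSTF1 replicate 1.

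In the oxidative stress list 0 of 5 members were called, and NDB2, a mitochondrial NAD(P)H dehydrogenase gene, differed by -0.56 (-0.96 to -0.16). NDB2 passed without AmGSTF1 replicate 2 (-0.75, adjusted p = 0.0247) and with array weights (-0.62, 0.0363), but was -0.39 (0.311) without AmGSTF1 replicate 1. The median of the list was 0.14 and its mean 0.0044, which turned negative under quantile, median and loess scaling, while camera's direction was down (adjusted p = 0.788). In leaf senescence 0 of 3 members were called, with WRKY53, a senescence regulator also in the oxidative stress list, at 0.46 (-0.08 to 1.01), a median of 0.46 and camera adjusted p = 0.501. In glucosinolate synthesis 0 of 4 were called, with UGT74B1 at -0.30 (-0.62 to 0.02). Its median was 0.0031 and its mean -0.04, again of opposite signs (camera adjusted p = 0.716).

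Lists with 1 or 2 measured members were not tested. Their leading members were AT1G53540 of the heat shock list at 0.38 (-1.99 to 2.74), the clock gene GI at 0.05 (-0.27 to 0.37), HAT2 of the auxin list at -0.24 (-0.52 to 0.05) and the iron regulator PYE at -0.40 (-0.85 to 0.04). AT1G53540 varied widely between replicates in both groups, with signals of 607, 54.9 and 16.5 in Col0 and 260, 21.5 and 287 in AmGSTF1. Herbicide targets, salicylate defence and hypoxia had 0 measured members.

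Markers of other cell types did not pass where measured. The root marker PYK10 differed by 0.63 (-0.21 to 1.48), the guard cell regulator FAMA, given as FMA in the table, by -0.55 (-1.09 to -0.02) and the vascular SWEET11 by 0.08 (-0.43 to 0.60). Adjusted over the list alone, FMA was lower, as the single measured member of its list. Epidermis, flower and cell division markers had 0 measured members, so a shift in tissue composition was tested here by these 3 genes alone.

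Of the 10 lists tested, 0 were higher and 0 lower with camera, with its estimated correlation or with fry after adjustment. At an unadjusted p under 0.05, camera and fry each had 2 lists, flavonoid synthesis and glutathione synthesis with sulfate assimilation, both lower. Over all 25 lists, 1 measured gene rose and 4 fell.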

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

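Dropping list members without a table symbol was chosen after the data were seen, and the RNA quality comparison was not run. Probe sets higher and lower in AmGSTF1 (292 and 396) numbered 123 and 213 with no filter on dim probe sets, where more were tested, 192 and 237 without the intensity trend, and 814 and 827 with array weights, which were lowest for both replicates 2 (0.645 and 0.602). At an adjusted p under 0.1 they numbered 745 and 777, and 135 and 96 at 2-fold or more. Leaving out 1 array gave 6 to 603 higher and 5 to 566 lower. None of the 688 calls changed sign under any setting in which it was tested. Their groups do not overlap, so only the normalizations between arrays could have changed a sign. The number of arrays alone does not explain the losses, since the count rose without either replicate 2. Beyond this the cause was not tested.

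No clear pairing by replicate number was seen. Deviations from the group means of same-numbered arrays correlated at 0.146, -0.027 and -0.050 across probe sets. Only replicate 1 of each group correlated best with its own number, and its 0.146 was the highest value of any pair. With 3 arrays per group this check cannot exclude an effect shared by same-numbered arrays. With a replicate block, 40 probe sets were higher and 38 lower, and 72 of these 78 were among the 688. Of the 25 called named genes, 12 were still called; GSTU27, AT1G06000, SIR, GT72B1 and JMT were not (adjusted p = 0.0564 to 0.0823), nor were AT5G24490, AT5G18600, AT5G44050, AT1G14120, CCR2, AT4G32340, AT3G47800 and AT3G12860 (0.0520 to 0.0833). LEA4-5 passed (0.0407).

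Gene lists lower numbered 1 in place of 0 with the dimmest 60% left out (flavonoid genes, adjusted p = 0.0381 at the preset correlation; the estimated one, which gave 0.581 with the dimmest 40% left out, was not tried there), and the range over omitted arrays was 0 to 1 for lists lower and 0 to 1 for lists higher. The mean of the oxidative stress list turned to -0.0035 (pseudocount 64), -0.028 (dimmest 60% left out), -0.027 (quantile), -0.056 (median centring), -0.018 (loess), -0.027 (array weights) and -0.028 (members without a symbol dropped), with -0.089 to 0.17 over omitted arrays. The abscisic acid list turned to -0.0029 with the dimmest 60% left out. The glucosinolate list turned to 0.022 with array weights and ranged from -0.16 to 0.17 over omitted arrays. APS4 turned to -0.045 (median centring) and -0.046 (array weights) and GI to -0.012 (median centring). Over omitted arrays, APS4 ranged from -0.098 to 0.23, GI from -0.018 to 0.12, AT1G53540 from -0.52 to 1.61 and SWEET11 from -0.17 to 0.30. None of the genes and lists whose sign turned passed its test, and each of these genes has an interval that includes 0. Without detection calls, signals near the floor, as for CYP51G2 in Col0, limit the size that can be given.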

Other observations

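The genes in this part were chosen after their values were seen, and so were the tests of variation among wild-type samples, time of day and mixing, the lists they use and the groups by gene name. Called genes outside the fixed lists included the following, which were not tested as a group. PWD, a phosphoglucan, water dikinase of starch breakdown, rose by 0.80 on the log2 scale, TMT1, a vacuolar sugar transporter, by 0.71, and SDP1, a lipase that degrades storage oil, by 1.04. MCCA, a subunit of methylcrotonyl-CoA carboxylase in leucine breakdown, rose by 1.89 and ALDH6B2, of valine breakdown, by 1.25. PORB, which makes chlorophyllide in the light, rose by 1.31, and PAM68, an assembly factor of photosystem II, by 1.23. Falls included Hsp70-2 (-1.38), TBL26 (-1.24), the calmodulin-like CML38 (-1.16), the pirin PRN (-1.13) and the calreticulin CRT1b (-0.84).

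Among 43 groups of at least 4 genes that share the letters of their symbols, 3 passed camera at the preset correlation. Of 4 MSRB genes, MSRB5, MSRB6 and MSRB9 fell, by 1.37, 1.89 and 1.61, while MSRB3 differed by 0.34 (adjusted p = 0.0122 for the group). Of 8 ATG genes of autophagy, ATG8F rose by 1.05 and 7 had higher values, and of 7 SWEET genes SWEET13 fell and 6 had lower values (adjusted p = 0.0347 for each). With an estimated correlation the adjusted p was 0.805 for all 3 groups. For MSRB that correlation was -0.0088, below the preset 0.01, yet the unadjusted camera p went from 0.000284 to 0.0211. The larger p of MSRB therefore cannot be credited to correlated members. The medians kept their sign under quantile, median and loess scaling.

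Called genes included PRH75, RBL and YAO, nucleolar proteins of ribosome production, which fell by 0.72, 0.80 and 0.85. A list of ribosome biogenesis genes was then written from general knowledge. Of its 30 measured members other than those that prompted it, 30 had lower values and 20 fell, with a median of -0.68 (quartiles -0.81 and -0.59), and the median was -0.60 to -0.81 without each array. Camera gave p = 7.35e-23 at the preset correlation, but p = 0.0584 with the estimated correlation of 0.593. The latter test also uses fewer degrees of freedom, so its p does not measure correlation alone. It did not show a shift of the set beyond that of correlated genes. The members' mean relative to all arrays was 0.42, 0.21 and 0.42 in Col0 replicates 1, 2 and 3 and -0.49, -0.14 and -0.43 in AmGSTF1.

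A growth or energy state that also varies between wild-type samples stays open. The difference of Col0 replicate 2 from 1 other Col0 array correlated across probe sets with the difference of AmGSTF1 from the remaining Col0 array, at r = 0.318 and 0.357 for the 2 choices. AmGSTF1 replicate 2 deviated towards Col0 in the same way (r = 0.365 and 0.196). Replicate 2 was chosen because it lay nearest the other group, and mixing would give such values too, so they restate that position and decide nothing on a shared state. A different time of day at harvest stays open too: of 4 measured evening-phased clock genes COR27, AT4G33980 and CCL rose by 1.63, 1.61 and 1.21, with a median of 1.41 over the 4, and GI differed by 0.05 (-0.27 to 0.37). COR27 and CCL had prompted this list, so the median says nothing on their change; over AT4G33980 and GI alone it was 0.83, from members that differ widely. Under quantile and loess scaling 2 of the 4 were called, and the measured morning-phased gene, AT4G01280, differed by -0.69 (-1.08 to -0.30, adjusted p = 0.0527 in limma's test). The effect of the transgene is the biological explanation the design names, and it was not tested apart from these.

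A list for carbon starvation and branched-chain amino acid breakdown, prompted by MCCA and ALDH6B2, had 10 of 11 other measured members with higher values and 0 called, with a median of 0.46 (camera p = 0.00766, or p = 0.124 with an estimated correlation). Neighbouring measured genes were both called in 1 direction in 9 places, against a mean of 9.53 over 10000 random placements (one-sided permutation p = 0.618).

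The number of calls was weighed against chance and scaling. The real grouping called 688 probe sets and the highest of the other splits 0, with 1 of the 10 splits reaching the real number. Every other split mixes the groups, so the difference between the groups widens its spread. The low counts there therefore do not weigh against chance, and 10 splits are too few for a share under 0.05. Unequal signal distributions of the arrays are argued against, since 92.7% of the calls remained under quantile normalization. The transgene and any unrecorded difference in handling between the groups stay open. The Col0 plants carried no transgene, so the enzyme's effect cannot be told apart from any other difference between transgenic and wild-type plants.

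Col0 replicate 2 lay towards the AmGSTF1 arrays, and RNA of AmGSTF1 leaves mixed into it could give that. For 38 probe sets at least 4-fold higher in AmGSTF1 than in the other Col0 arrays, the median share of AmGSTF1 signal needed was 20.4% (quartiles 12.1% and 55.1%), and for 313 under 2-fold higher it was 54.0% (quartiles 27.4% and 76.2%). Mixing needs 1 share for all genes; the medians differ while the quartiles overlap, so mixing is not excluded. CYP51G2 would need 3.01% and AT1G43590 9.87%, though 2 genes chosen for their low Col0 signal do not decide it. A leaf state shared with AmGSTF1 stays open as the biological alternative.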
